A study of Mus musculus with 3 samples.

How the data were processed

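The series holds 3 samples of mPTECs, 1 each from cells straight after isolation (day 0) and after 1 and 3 days on culture dishes. Per the labels, total RNA was extracted with TRIzol, amplified with a low-input linear amplification kit and labelled with Cy3, and 1 sample was hybridised to each Agilent mouse 1-colour array. The 3 arrays lay on 1 slide and were scanned on 1 day. Per the file headers, Feature Extraction version 10.5.1.1 measured the spots, whereas the submitters' processing notes name version 9.1. The deposited array files give each spot's processed signal as an intensity, background subtracted and corrected for spatial trends, and not normalized between arrays. Per the file headers, the other columns used here were the mean signal, the local background and the background-subtracted signal, each an intensity, and flags of other kind, set to 0 or 1, for spots well above background, saturated spots and outliers. A multiplicative trend correction was applied on 2 arrays, those of day 0 and day 1, but not on that of day 3. The authors also deposited a value table whose unit is a ratio, the processed signal of a spot over the 75th percentile of its array, on a linear scale. This was tested on the files: all 43379 values of each array lay within 0.001 of that ratio.

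Each array held 45018 spots, of which 1639 were controls and the rest belonged to 41174 probes. The signal was taken as the log2 processed signal minus the 75th percentile of the array's non-control spots, in the authors' manner. Spots with an outlier flag were left out (94, 102 and 85 on the arrays of day 0, day 1 and day 3), as were 17 probes that had no other spot, and no spot was saturated. Spots of 1 probe were averaged. Probes were named by their transcript accession in the RefSeq table of mouse genes (26888 probes), failing that by symbol (5025) or by an unambiguous synonym (832), and 8429 probes stayed without a gene name and outside the comparisons. A gene was represented by the probe with the highest mean over the 3 arrays, which gave 19862 genes, 19143 of them well above background on at least 1 array. Probe positions are those of the array files, on mm9.

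Each comparison took genes well above background on at least 1 of its arrays. A gene was so if any of its probes was. Where the probe standing for the gene was not well above background on 1 array, the ratio was a bound, taken against the lowest signal well above background on that array or the gene's own signal there if higher, and is given as "at least". These lowest signals were 1.14%, 1.06% and 0.669% of the 75th percentile. Genes were counted from a 4-fold difference, a log2 ratio of 2, in each direction. With 1 array per day there was no test, no p-value and no error between samples, and the number of arrays limits the precision. The spread between spots of a probe was taken from 666 values of probes with at least 5 spots on an array, and that between probes of a gene from 8004 genes.

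There were 29 gene lists and 9 lists of cell type markers, fixed before the data were examined. A list's median covers members well above background on at least 1 array, and was placed among 10000 random lists of the same size, matched on mean signal in 20 bins. The lists cover apical and basolateral transporters, brush border and endocytic receptor genes, transcription factors and coactivators of the proximal tubule, fatty acid oxidation and peroxisomes, oxidative phosphorylation and the citrate cycle, glycolysis, gluconeogenesis and fructose metabolism, amino acid metabolism, and drug, steroid and vitamin D metabolism. Others cover tubule injury, mesenchymal and matrix genes, junctions and keratins, the actin cytoskeleton, Yap and Tead targets, G1/S and DNA replication, G2/M and mitosis, Trp53 targets and cell cycle inhibitors, immediate early genes, cytokines and NF-kB targets, the interferon response, Nrf2 and oxidative stress, unfolded protein and integrated stress, heat shock, cholesterol, glucocorticoid induced genes, the nephron progenitor, ribosomal proteins and reference genes. Lists of cornified envelope, keratinocyte, urothelium and mesothelium genes were added after the data had been seen. A few members of the fixed lists, such as Pck1, Lif and Amt, gave no value.

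By a rule fixed in advance, the 12 genes with the largest ratio in each direction were named among genes well above background and not saturated on both arrays, and the 4 with the largest bound. Clone and prediction names were left out. So were genes whose other probes well above background on either array ran the other way, or the same way by less than 2-fold. Members of the fixed lists could be named as examples. Members that ran against their list, the mesothelial genes and the other genes given among the further observations, were chosen after their values were seen. A few genes the rule or the lists hold are not reported here.

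The alternatives were centring on the median, quantile normalization, normexp background correction (limma 3.58.1 in R 4.3.3, offset 50) on the mean signal and local background, the authors' value table, scaling to 10 spike-in control probes or to the 12 reference genes, the mean of a gene's probes, genes well above background on all 3 arrays only, no filter on dim genes, outlier spots kept with saturated ones left out, and thresholds of 2-fold and 8-fold. The mean of a gene's probes took in all of them, also those not well above background. Spike-in signals followed their stated concentrations with slopes of 0.963, 0.959 and 0.967 on the log scale (r2 of 0.994, 0.993 and 0.995). The signal without the multiplicative trend correction was added as an alternative after the data had been seen. The method was tested on simulated data for day 3 against day 0 with 19143 genes and 200 genes given a known difference. All 50 genes with a log2 difference of 3 and all 50 with 4 were called, none of those with 1 or 1.5 was, and there were 0 false calls. The simulated spread was that between spots alone, 0.195 for a log2 ratio, so the 4-fold threshold fixed these outcomes. All simulated genes were taken as well above background, and differences between samples or between probes of a gene were not simulated. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.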

Results

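Gene expression was measured in mPTECs, primary kidney cells taken from male mice of 1 month, straight after isolation (day 0) and after 1 or 3 days on culture dishes. The abbreviation is used as the labels give it. The culture medium held insulin, transferrin, selenium, hydrocortisone and 1% serum. Each day was represented by 1 Cy3-labelled sample on 1 Agilent array of 41174 probes, so no difference between days has a replicate check, no test was made, and the folds below describe these 3 arrays. The 75th percentile of the signal was 1184, 1509 and 1515 intensity units on the day 0, day 1 and day 3 arrays, and 18744, 18612 and 18871 named genes were well above background. Spots of the same probe differed with a median SD of 0.138 on the log2 scale, which alone gives a ratio between arrays a spread of 0.195, or 1.14-fold. Different probes of a gene differed more, with a median SD of the log2 ratio of 0.36 for day 1 against day 0, 0.50 for day 3 against day 0 and 0.29 for day 3 against day 1. Signals are given on the log2 scale relative to the 75th percentile of their array. Against that percentile, the spike-in controls stood at -0.14 on day 1 and -0.50 on day 3 relative to day 0, the median of all spots at -0.21 and -0.31, and the median of 12 reference genes at 0.32 and 0.25. Scaling to any of these instead moves every ratio by the same amount.

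The comparison of day 1 with day 0 asks how far expression had departed from that of the fresh cells after the first day on a dish. On the day 1 array, genes that mark the proximal tubule were lower, as were transporters, enzymes of fatty acid oxidation, gluconeogenesis and amino acid metabolism, and immediate early genes. Genes of tubule injury, the actin cytoskeleton, DNA replication and the interferon response were higher. All 14 proximal tubule markers were lower, 11 of them at least 4-fold, with a median log2 ratio of -2.86. Of 26 injury genes, 12 were at least 4-fold higher and 3 at least 4-fold lower, with a median of 1.83. Among 18895 genes, 638 were at least 4-fold higher and 973 at least 4-fold lower, so the higher genes made up 39.6% of these calls. That share was 51.7% with arrays centred on their median and 24.9% with scaling to the reference genes.

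Of the genes taken by rank, Crct1 came first. This gene of the epidermal cornified envelope, whose probe lies at 92818192 to 92818251 on chromosome 3 (mm9), was 491-fold higher. Other genes of that structure were high as well: Sprr2f was 334-fold, Sprr1a 113-fold and Sprr2h 91.8-fold higher. Grp, which encodes gastrin-releasing peptide, was 407-fold higher, and the stromelysin gene Mmp3 was 277-fold higher. Hk2, a hexokinase of the first step of glycolysis, was 246-fold higher. Il1rn, the interleukin 1 receptor antagonist, was 242-fold higher by its brighter probe, and its other probe gave a log2 ratio of 4.94. The prolactin family gene Prl2c5 was 178-fold higher and Il1f6, an interleukin 1 family cytokine, 125-fold higher. Areg, which encodes the growth factor amphiregulin, was not well above background on day 0 and was at least 54.6-fold higher on day 1. S100a7a was at least 20.4-fold higher. With normexp background correction, which draws dim signals together, Areg, S100a7a and Sprr2h had log2 ratios of 3.35, 2.26 and 4.50.

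The injury genes held some of the largest differences. Krt20, a keratin of simple epithelia, was 138-fold higher, and Havcr1, the gene of kidney injury molecule 1, was 97.5-fold higher. S100a6 was 62.3-fold higher, Cd44, a hyaluronan receptor, 54.7-fold and Lcn2, the gene of the iron-carrier protein lipocalin 2, 25.3-fold. The fibrinogen chains ran the other way, with Fgg 7.70-fold and Fga 4.77-fold lower. Fga was under 4-fold with normexp, at -1.85 in log2 ratio, and the mean of the Cd44 probes gave 3.71. Of 29 genes of the actin cytoskeleton, 8 were at least 4-fold higher and 1 at least 4-fold lower (median 1.57), the latter being the myosin light chain Myl9, 29.9-fold lower. The actin-binding genes Capg and Pdlim7 were 9.53-fold and 7.52-fold higher. Of 30 genes of G1/S and DNA replication, 16 were at least 4-fold higher (median 2.09), among them Uhrf1 at 19.2-fold, the helicase subunit Mcm3 at 18.0-fold and the licensing factor Cdc6 at 12.3-fold. Of 33 genes of G2/M and mitosis, 5 were at least 4-fold higher and the median was 0.67. Cdc20 and Ccnb1, which act in mitosis, had log2 ratios of 0.23 and -0.72, each of which takes the other sign under some alternative. Of 21 Trp53 targets and cell cycle inhibitors, 6 were at least 4-fold higher and 2 at least 4-fold lower. The inhibitor Cdkn1a was 11.3-fold and Eda2r at least 23.0-fold higher (a log2 ratio of 2.22 with normexp), and Btg2 was 12.6-fold lower.

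Among the stress groups, 8 of 22 interferon response genes were at least 4-fold higher (median 1.35): Usp18 was 12.9-fold, Oas1a 11.6-fold and Ifit1 8.01-fold higher, while Irf1 was 8.02-fold lower. Of 21 genes of the Nrf2 and oxidative stress list, 9 were at least 4-fold higher and 1 at least 4-fold lower (median 1.08), led by the cystine transporter gene Slc7a11 at 48.7-fold and the heme oxygenase gene Hmox1 at 9.31-fold. The unfolded protein and integrated stress list was divided. Its median of 0.03 takes the other sign with reference gene scaling and quantile normalization, with Trib3 88.3-fold, the asparagine synthetase gene Asns 32.2-fold and the mitochondrial folate enzyme gene Mthfd2 26.6-fold higher, and the chaperone gene Hspa5 near its day 0 level. Of 30 cytokines and NF-kB targets, 7 were at least 4-fold higher (median 0.84). The chemokine Ccl20 was 88.0-fold and Ccl5 43.1-fold higher, and Il1b, the gene of interleukin 1 beta, was 27.2-fold lower. Immediate early genes were lower, 13 of 26 at least 4-fold (median -1.94). Fos was 104-fold, Fosb 27.9-fold and Nr4a1 17.6-fold lower, whereas Fosl1 was 25.7-fold higher. The heat shock genes Hspa1a and Hspa1b were 10.4-fold and 10.03-fold lower, in a list of 14 genes whose median of 0.29 takes the other sign with reference gene scaling.

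Downward, the first gene by rank was Slc5a12, a sodium-lactate cotransporter gene of the proximal tubule with a probe at 110487726 to 110487785 on chromosome 2 (mm9). It was 139-fold lower by its brighter probe, while its other probe gave a log2 ratio of -1.18. Of 35 apical transporters, 22 were at least 4-fold lower and none was at least 4-fold higher (median -2.63). The monocarboxylate transporter Slc5a8 was 44.5-fold lower, the fructose transporter Slc2a5, which stood outside the list, 54.6-fold, and the phosphate transporter Slc34a1 8.20-fold. Of 19 basolateral transporters, 13 were at least 4-fold lower (median -2.65), and of 27 brush border and endocytic receptor genes, 17 (median -2.48). The endocytic receptors Lrp2 and Cubn were 18.5-fold and 14.9-fold lower. Of 16 transcription factors and coactivators, 7 were at least 4-fold lower (median -1.77), among them Hnf4a at 8.87-fold and Ppara at 9.63-fold, while Pax8 lay within 2-fold.

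Several metabolic lists were lower too. Of 36 genes of fatty acid oxidation and peroxisomes, 16 were at least 4-fold lower (median -1.90), for example Ehhadh at 14.3-fold. Of 12 genes of gluconeogenesis and fructose metabolism, 6 were at least 4-fold lower (median -1.98), with glucose 6-phosphatase, G6pc, 50.9-fold lower. Of 30 genes of amino acid metabolism, 19 were at least 4-fold lower (median -2.45), and of 25 genes of drug, steroid and vitamin D metabolism, 13 (median -2.06), where the vitamin D 24-hydroxylase Cyp24a1 was 31.7-fold lower. The oxidative phosphorylation and citrate cycle list had a median of -0.72, with 1 of 39 genes at least 4-fold lower. Other lists ran the other way: glycolysis genes had a median of 0.53, at percentile 74.7 of 10000 random lists matched on expression, and cholesterol genes one of 0.73. Outside these lists, the insulin-like growth factor binding protein gene Igfbp1 was 131-fold lower, the succinate receptor gene Sucnr1 64.6-fold, the glycosyltransferase gene Mgat3 62.8-fold by its brighter probe, Acnat2 66.3-fold, Clec2h 60.3-fold, Nepn 51.6-fold and Hsd3b2 46.3-fold. The 3 probes of Hsd3b2 ran from -5.53 to -1.71 in log2 ratio. Genes not well above background on day 1 had bounds only. Slitrk1 and Serpind1 were at least 13.5-fold and 12.8-fold lower, and both were under 4-fold with normexp, at -1.90 in log2 ratio. For some genes of this comparison another probe gave a far smaller ratio, in log2 4.43 for Prl2c5, 2.75 for Trib3, 1.32 for Eda2r, 3.42 for Slc7a11, 0.27 for Cd44, -0.89 for Hnf4a, -1.84 for Lrp2 and -2.28 for Mgat3.

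The comparison of day 3 with day 0 spans the whole time in culture. On the day 3 array the proximal tubule markers were lower still, and genes of cell division, cytokines, tubule injury and the cytoskeleton were higher. All 14 proximal tubule markers were at least 4-fold lower, with a median log2 ratio of -5.72. Of 33 genes of G2/M and mitosis, 31 were at least 4-fold higher, with a median of 5.29. Of 30 cytokines and NF-kB targets, 20 were at least 4-fold higher and none at least 4-fold lower (median 2.41). Among 18998 genes, 1017 were at least 4-fold higher and 1519 at least 4-fold lower, and the higher genes made up 40.1% of these calls. That share was 55.9% with median centring, 29.1% with reference gene scaling and 65.1% with spike-in scaling, under which 1748 genes were higher and 936 lower.

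**Figure D1:**
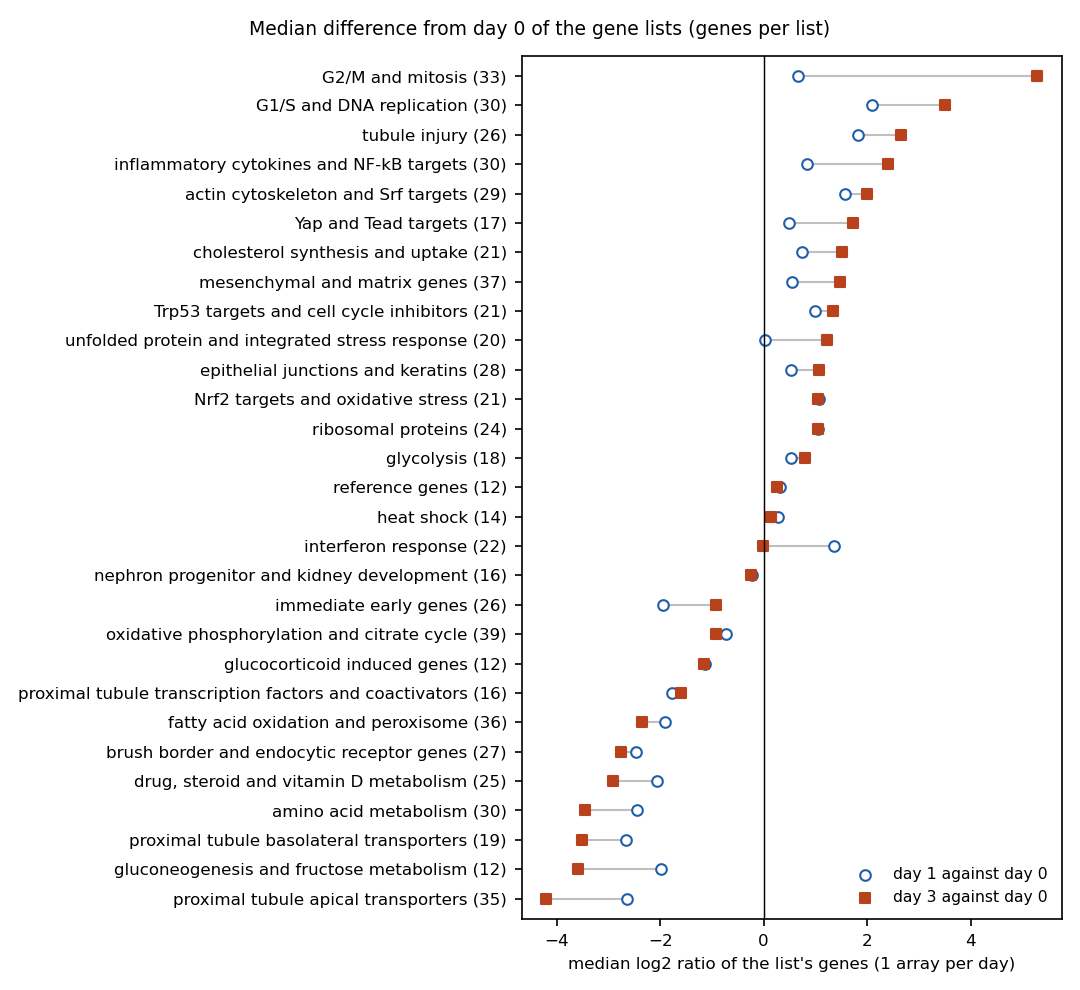
Median log2 ratio of each gene list (rows, with the number of genes measured) against day 0, for day 1 (open circles) and day 3 (filled squares), with 1 array per day; a grey line joins both values of a list. The G2/M and mitosis genes lie at 0.67 on day 1 and 5.29 on day 3, and the interferon response genes at 1.35 and -0.01, the last a value whose sign depends on the scaling.

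Cytokine genes were among the first by rank. Ccl20, a chemokine gene with its probe at 83115500 to 83115559 on chromosome 1 (mm9), was 1191-fold higher. The monocyte chemoattractant gene Ccl2 was 214-fold higher, Csf2, the gene of the growth factor GM-CSF, 164-fold, Cxcl2 89.3-fold and Cxcl1 53.0-fold. Cxcl5, not well above background on day 0, was at least 133-fold higher. Msln, which encodes the surface protein mesothelin, was 369-fold higher, and Trib3, a target of the stress factor Atf4, 162-fold. Crct1, Sprr1a and Sprr2f were 668-fold, 201-fold and 165-fold higher, and S100a7a at least 75.5-fold. Ska1, of the mitotic spindle, and the filamin gene Flnc were 284-fold and 249-fold higher by their brightest probes, but other probes of these genes gave log2 ratios down to 1.67 and 1.16. With normexp, Cxcl5, Csf2 and S100a7a had log2 ratios of 4.63, 5.35 and 3.78.

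Of the cell division genes, Cdk1, the kinase that drives entry into mitosis, was 103-fold higher, Top2a 97.0-fold, Birc5 100.3-fold, Plk1 65.0-fold and the proliferation marker Mki67 56.1-fold. Aurkb, a mitotic kinase gene not well above background on day 0, was at least 111-fold higher. Cks2 lay within 2-fold of day 0, as did Bub1 by its brightest probe, although the mean of the Bub1 probes gave a log2 ratio of 3.36. The same mean was 3.96 for Cdk1 and 3.41 for Top2a, and with normexp Aurkb stood at 4.45. Of 30 genes of G1/S and DNA replication, 28 were at least 4-fold higher (median 3.50). The Trp53 targets and cell cycle inhibitors had a median of 1.34, 6 genes at least 4-fold higher and 2 at least 4-fold lower, with Eda2r at least 36.0-fold (a log2 ratio of 2.80 with normexp) and Cdkn1a 9.36-fold higher and the antiproliferative gene Btg2 8.09-fold lower.

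Of the injury genes, 16 of 26 were at least 4-fold higher and 2 at least 4-fold lower (median 2.65). Cd44 was 134-fold, Havcr1 114-fold, the calcium-binding gene S100a6 90.9-fold, Timp1, a metalloproteinase inhibitor, 35.6-fold and vimentin, Vim, 15.6-fold higher. The mean of the Cd44 probes gave a log2 ratio of 4.89. Spp1, which encodes osteopontin, and Clu lay within 2-fold. Of 37 mesenchymal and matrix genes, 12 were at least 4-fold higher and none at least 4-fold lower (median 1.48): the laminin chain Lamb3 was 91.1-fold and fibronectin, Fn1, 14.3-fold higher, whereas the transcription factor Snai1 had a log2 ratio of -1.58. Of 28 junction and keratin genes, 8 were at least 4-fold higher, including Krt19 at 106-fold and Krt18 at 14.3-fold. The claudins Cldn10 and Cldn2 were 11.6-fold and 9.25-fold lower, and E-cadherin, Cdh1, had a log2 ratio of 0.52. Of 29 genes of the actin cytoskeleton, 14 were at least 4-fold higher and 1 at least 4-fold lower (the median being 3.99-fold higher), and of 17 Yap and Tead targets, 8, led by Ankrd1 at 155-fold. The day 1 medians of the mesenchymal, junction and Yap lists were 0.55, 0.53 and 0.49.

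Downward, Ces1d, a carboxylesterase gene, was 502-fold lower, and the phosphate transporters Slc34a3 and Slc34a1 477-fold and 419.7-fold. The probe of Slc34a1 lies at 55515201 to 55515259 on chromosome 13 (mm9). The aldo-keto reductase Akr1c21 was 405-fold lower, the cytochrome P450 genes Cyp2d26 and Cyp2d12 353-fold and 281-fold, Rdh16f2 296-fold and Spp2 237-fold. Slc2a5 was 227-fold lower, Acnat2 233-fold and Hsd3b2 303-fold, with the mean of the Hsd3b2 probes at -5.24 in log2 ratio. The brighter probe of the brush border protease Mep1b was not well above background on day 3 and was at least 168-fold lower, or -4.83 in log2 ratio by the mean of its probes and -4.81 with normexp. Genes not well above background on day 3 were led by Slc22a29, at least 653-fold lower, the fatty acid binding protein gene Fabp1, at least 651-fold, Cyp2e1, at least 610.0-fold, and Slc22a28, at least 307-fold. With normexp these 4 genes stood at -6.29, -6.13, -6.36 and -5.47 in log2 ratio. Of the apical transporters, 24 of 35 were at least 4-fold lower (median -4.20), and of the basolateral ones 13 of 19 (median -3.50). The sodium-glucose cotransporter Slc5a2 was 58.0-fold, the sodium-proton exchanger Slc9a3 133-fold and the organic anion transporter Slc22a6 109.7-fold lower. The mean of the Slc9a3 probes gave a log2 ratio of -4.20. Abcc4, an efflux pump gene, was 2.74-fold higher. Brush border and endocytic receptor genes had a median of -2.76, with 21 of 27 at least 4-fold lower. Transcription factors and coactivators had a median of -1.60, with Hnf4a 10.6-fold lower.

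Of the metabolic lists, those of glycolysis and cholesterol had medians above 0 on day 3 and the others were lower. Amino acid metabolism had 24 of 30 genes at least 4-fold lower (median -3.45), including Miox, which oxidises inositol, at 103-fold and Hgd, of tyrosine breakdown, at 119-fold. Gluconeogenesis and fructose metabolism had 8 of 12 (median -3.58), with Fbp1 98.7-fold lower and Pck2, the mitochondrial phosphoenolpyruvate carboxykinase, 5.93-fold higher. Fatty acid oxidation had 19 of 36 (median -2.34), drug, steroid and vitamin D metabolism 15 of 25 (median -2.90), and oxidative phosphorylation 1 of 39 (median -0.93). Of 18 glycolysis genes, 4 were at least 4-fold higher and 1 at least 4-fold lower (median 0.80, percentile 93.7 of the random lists): Hk2 was 367-fold, the lactate exporter Slc16a3 22.7-fold, the pyruvate kinase Pkm 5.66-fold and the glucose transporter Slc2a1 5.10-fold higher. Pkm was under 4-fold by the mean of its probes, at 1.60 in log2 ratio. Cholesterol synthesis and uptake genes had a median of 1.52, with Fdps 18.5-fold higher. The 24 ribosomal protein genes had medians of 1.04 on day 1 and 1.05 on day 3, none of them 4-fold different, and the glucocorticoid induced genes medians of -1.14 and -1.16, with Pdk4 22.6-fold lower on day 3.

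Of the stress lists, the Nrf2 and oxidative stress genes had a median of 1.06, with 5 at least 4-fold higher and 3 at least 4-fold lower, and the unfolded protein and integrated stress genes one of 1.22, with Asns 29.1-fold higher. Immediate early genes had a median of -0.92, with 10 of 26 at least 4-fold lower, among them Fos at 39.5-fold, and 1, Fosl1, at least 4-fold higher. Heat shock genes had a median of 0.14, with the chaperone Cryab 17.7-fold higher and Hspa1a 13.2-fold lower, and nephron progenitor and kidney development genes medians of -0.22 on day 1 and -0.25 on day 3. The signs of the heat shock median and of the day 3 progenitor median depend on the scaling, and that of the day 1 progenitor median turns with quantile normalization. In the progenitor list, 4 of 16 genes were at least 4-fold higher and 1 at least 4-fold lower on day 3, the former including Wnt7b at 5.44-fold. Other probes gave far smaller ratios on day 3 for Trib3 (3.80 in log2), Eda2r (2.02), Cryab (0.84), Fdps (1.20), Fn1 (1.20), Vim (0.41), Cd44 (0.81), Cdk1 (1.24), Top2a (0.33), Pkm (0.34), Hnf4a (-0.87), Hsd3b2 (-2.15), Slc9a3 (-1.34) and Mep1b (-1.33). As a description of these arrays, the medians of the proximal tubule marker, transporter, fatty acid, amino acid, gluconeogenesis and drug metabolism lists lay below those of all 10000 random lists on day 1 and day 3, and the injury, actin, G1/S and G2/M lists above them. Also below all of them on both days were the brush border, transcription factor and oxidative phosphorylation lists. The same held for the markers of the loop of Henle and of the distal tubule and collecting duct. Not all of these lists are separate results. Every proximal tubule marker is also held by the transporter, brush border, fatty acid, amino acid, gluconeogenesis or drug metabolism list.

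**Figure D2:**
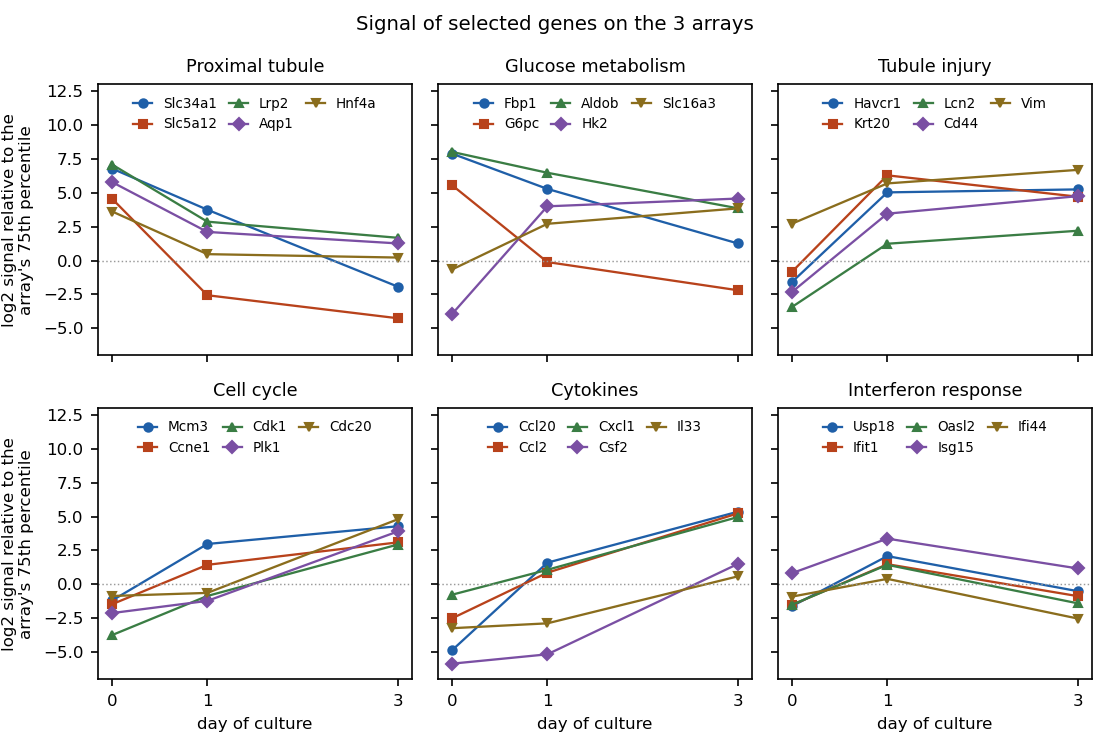
Signal of 30 genes (log2, relative to the 75th percentile of each array, dotted line) against day of culture (0, 1 and 3), 5 genes per panel and 1 array per day. Slc34a1 stands at 6.79, 3.75 and -1.92, Plk1 at -2.12, -1.23 and 3.90, and Isg15 at 0.82, 3.37 and 1.17 on days 0, 1 and 3.

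The comparison of day 3 with day 1 separates the later part of the culture from the first day. Mitosis genes and several cytokine genes were higher on day 3, interferon response genes were lower, and the proximal tubule markers, all lower on day 1 already, were lower still. Of 33 genes of G2/M and mitosis, 30 were at least 4-fold higher than on day 1 (median 4.15), against 6 of 30 G1/S genes (median 1.54). Among 18920 genes, 307 were at least 4-fold higher and 249 at least 4-fold lower, a share of 55.2% higher, which was 76.9% with spike-in scaling (494 higher, 148 lower). With normexp background correction 132 genes were lower.

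Csf2, whose probe lies at 54060772 to 54060799 on chromosome 11 (mm9), was 102-fold higher than on day 1, Cxcl5 70.8-fold and Ppbp, a platelet chemokine gene, 86.7-fold. The cell division genes Pimreg, Cdkn3, Cdc20, Ube2c, Cdca3, Iqgap3, Plk1 and Sapcd2 were 98.3-fold, 88.6-fold, 43.2-fold, 41.6-fold, 35.9-fold, 35.4-fold, 34.9-fold and 32.5-fold higher. Msln was 40.3-fold higher, and Erfe, the gene of the hormone erythroferrone, at least 46.1-fold. Entpd3 and Spink12 were at least 10.9-fold and 8.02-fold higher, and both were under 4-fold with normexp, at 1.88 and 1.31 in log2 ratio, while Erfe stood at 3.33. By the mean of their probes, Cdkn3 had a log2 ratio of 3.93 and Iqgap3 one of 2.30. These means take in a probe of each gene that was not well above background on either array. The Cdkn3 probes that were gave 4.59 to 6.47, and the Iqgap3 probe that was gave 5.15. Of 30 cytokines and NF-kB targets, 13 were at least 4-fold higher (median 1.56), including Ccl2 at 20.8-fold and Il33, an alarmin gene, at 11.1-fold, while Ccl5 was 4.77-fold lower, or under 4-fold with spike-in scaling, at -1.90 in log2 ratio. Yap and Tead targets had a median of 1.01, with 3 of 17 at least 4-fold higher.

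Of 22 interferon response genes, 6 were at least 4-fold lower than on day 1 and none at least 4-fold higher (median -1.08), among them Oasl2 at 7.16-fold, Ifi44 at 7.62-fold and Isg15 at 4.59-fold lower. Isg15 was under 4-fold with normexp, with spike-in scaling and without the multiplicative trend correction, at -1.80, -1.84 and -1.82 in log2 ratio. Against day 0 the list had a median of -0.01 on day 3, a value whose sign depends on the scaling. Slc34a3, with its probe at 25084438 to 25084497 on chromosome 2 (mm9), was 65.3-fold lower than on day 1, Cyp2d26 54.5-fold, Slc34a1 51.2-fold, Spp2 49.5-fold and Akr1c21 42.5-fold. The DNA endonuclease Dnase1 was 33.1-fold lower, Miox 27.3-fold, Ces1d 26.6-fold, the fatty acid hydroxylase Cyp4a14 19.99-fold and Mmp3 31.3-fold, the last from its high level on day 1. Cyp2e1, Slc22a29 and Fabp1 were at least 53.1-fold, 46.5-fold and 27.0-fold lower, and stood at -3.01, -2.67 and -2.01 in log2 ratio with normexp. Of the proximal tubule markers, 8 of 14 were at least 4-fold lower (median -2.77), and of the amino acid metabolism genes 9 of 30 (median -1.12). The proximal tubule transcription factors had a median of -0.06, with Hnf4a at a log2 ratio of -0.25, and the fatty acid oxidation genes one of -0.29. The signs of both medians and of the Hnf4a value turn with spike-in scaling, and that of the first with other alternatives too.

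Most genes at least 4-fold from day 0 on the day 1 array were so on the day 3 array too, 77.2% of the higher and 85.5% of the lower ones. Of 18840 genes compared on both days, 636 were at least 4-fold higher on day 1, 1010 on day 3 and 491 on both, where independent lists would share 34.1. For lower genes the numbers were 973, 1519 and 832, against 78.4. Simulated arrays that differ by the spread between spots alone shared 0 genes, which the 4-fold threshold fixes. The day 0 array serves both comparisons, so part of the excess may come from it. No gene was at least 4-fold higher on 1 day and at least 4-fold lower on the other. Of the 636 genes, 118 were at least 2-fold higher on day 3 than on day 1 and 65 at least 2-fold lower, such as Mmp3 and Grp, the latter 6.24-fold lower. Of the 973 lower genes, 284 were at least 2-fold lower still and 79 at least 2-fold higher than on day 1. Cyp24a1 was among the latter at 6.27-fold.

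Markers of other kidney cells were measured on the same arrays. Those of the loop of Henle and of the distal tubule and collecting duct were present on day 0, with uromodulin, Umod, at 7.98 and the water channel gene Aqp2 at 3.46, and their medians were -2.17 and -2.40 on day 1 and -3.86 and -2.85 on day 3. The loop marker Egf was 165-fold and the distal marker Calb1 55.3-fold lower on day 3, while another loop marker, Bst1, was 8.76-fold higher. Podocyte markers had medians of -2.11 and -1.67, with nephrin, Nphs1, 11.9-fold lower on day 3. Endothelial markers had medians of -0.64 and -2.18, with the receptor gene Kdr 10.8-fold lower on day 3. Red blood cell markers had medians of -2.56 and -2.47, with the globin gene Hbb-bt 189.6-fold lower on day 3, and another of its probes at -3.34 in log2 ratio. Fibroblast and mural cell markers had medians of -0.11 and -0.06, macrophage and dendritic cell markers -0.35 and -0.18, and lymphocyte markers -0.59 and -0.76. The signs of the fibroblast medians and of the day 3 macrophage median depend on the scaling. Within these lists, Col1a1 and Col1a2, genes of fibrillar collagen, were 7.12-fold and 4.02-fold higher on day 3, the macrophage marker Cd68 was 12.2-fold higher on day 1 and 5.07-fold on day 3, and the antigen presentation gene Cd74 was 14.1-fold lower on day 3. By the mean of their probes, Col1a1 and Col1a2 were under 4-fold, at 1.20 and 1.47 in log2 ratio, with another Col1a1 probe at -0.21, and Cd68 was on day 3 with normexp, at 1.99. Col1a2 was under 4-fold with 4 other alternatives as well, at 1.92 with quantile normalization, 1.92 with normexp, 1.76 with reference gene scaling and 1.94 without the multiplicative trend correction.

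**Figure D3:**
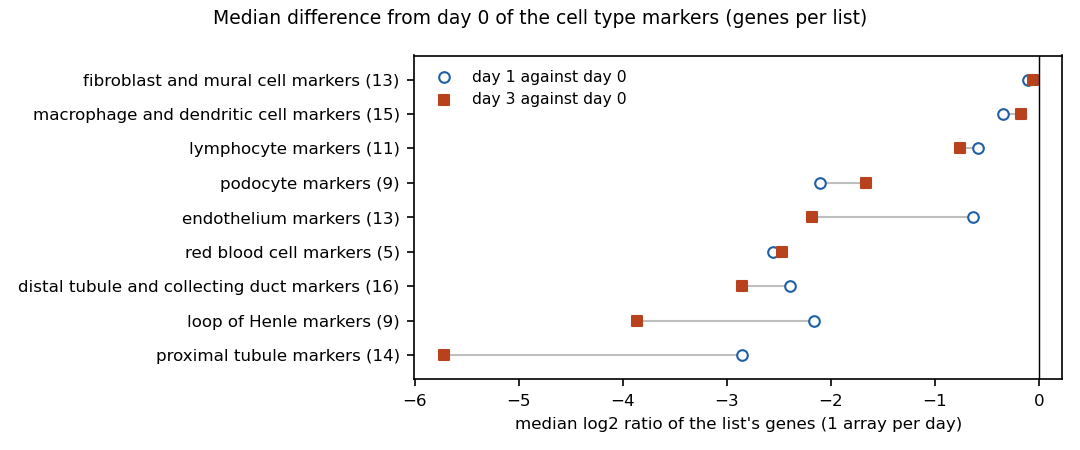
Median log2 ratio of the marker genes of each cell type (rows, with the number of genes measured) against day 0, for day 1 (open circles) and day 3 (filled squares), with 1 array per day. The proximal tubule markers lie at -2.86 on day 1 and -5.72 on day 3, and the fibroblast and mural cell markers at -0.11 and -0.06, values whose sign depends on the scaling.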

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

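The tests on the loop of Henle, distal tubule, collecting duct, podocyte and endothelial markers, on Dcn and Lum, on leukocyte RNA, on Krt14 and on Upk1a and Upk3a were chosen after the results were seen, as were the cornified envelope, keratinocyte, urothelium and mesothelium lists.

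Of the named and listed genes, 3 lay at least 2-fold from day 0 in opposite directions on day 1 and day 3. Col1a2 had log2 ratios of -1.85 on day 1 and 2.01 on day 3, Ifi44 of 1.31 and -1.62, and Ppbp of -1.67 and 4.77. With 1 array per day, the difference between the days was not tested for any of them. Signal also appeared in probes outside the comparisons: of 5847 probes without a gene name and well above background on both arrays, 77 were at least 4-fold higher on day 3 than on day 0 and 456 at least 4-fold lower. What these probes measure was not analysed here.

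The first pattern is the lower signal of the proximal tubule markers on day 3. Loop of Henle, distal tubule, collecting duct, podocyte or endothelial cells in their place would have their own markers higher if they kept them. The 4 medians of these markers ran from -3.86 to -1.67. Cells of these kinds that lost their markers in culture cannot be seen this way, so they stay open. Fibroblasts as the whole source would bring Dcn and Lum, abundant in these cells, if they kept them. Yet the log2 ratios of these genes were -0.96 and -0.80. Col1a1, Col1a2 and Col3a1 were higher, and the median of the 5 genes, 1.61, lay between the bounds of 1 and 2 set in advance. That median is the value of Col3a1 by its brighter probe. Its other probe gave 0.19, which would bring the median under 1. The result thus depends on the probe. A smaller share of fibroblasts stays open, as do fibroblasts that lost Dcn and Lum in culture. Mesothelial cells stay open too: Msln was 369-fold and Upk3b 15.5-fold higher, Lrrn4 was 2.10-fold higher and Wt1 3.18-fold lower, and 7 further markers had a median of 0.13, but ran from -2.81 (Gpm6a) to 5.54 (Slpi, whose other probe gave -1.79). Of the 7, 2 were at least 4-fold higher, where the rule set in advance for a negative result allowed at most 1. By the mean of its probes Slpi, 1 of these 2, was under 4-fold, at 1.87 in log2 ratio, so the outcome depends on its probe. Processing did not account for the pattern, as the marker median nearest 0 over the alternatives was -5.06. Degraded day 3 RNA would lower the ratio of the probe nearer the 5' end of a transcript. Over 4937 pairs of probes on the same transcript, well above background on day 0 and day 3, that ratio was higher by a median of 0.26. On day 0 the signal of these 5' probes relative to the 3' ones had a median of -1.51. Transcripts with a probe too dim on day 3 fell outside these pairs, so degradation was not tested for them. A loss of the differentiated state with days in culture may be the source, a hypothesis that was not tested, and day and array cannot be told apart because each day had 1 array.

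The next pattern is the higher signal of interferon response genes on day 1. More leukocyte RNA as the whole source would bring most leukocyte markers with it, but the higher of the macrophage and lymphocyte medians on day 1 was -0.35 and the macrophage gene Lyz2 had a log2 ratio of -0.98, although Cd68, 1 of 15 macrophage markers, was 12.2-fold higher, so a smaller share stays open. Scaling and signal processing left the list's median at 1.03 or above in all alternatives tried. A response of the cells to isolation or plating may be the source, which was not tested, and with 1 array the day and the array cannot be told apart here.

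The last pattern is the higher signal of cornified envelope genes in culture, where 12 of 41 genes on day 1 and 13 on day 3 were at least 4-fold higher and 3 and 1 at least 4-fold lower, with medians of 0.25 and 0.60, the first of which takes the other sign with reference gene scaling (-0.07). Keratinocytes as the whole source would bring Krt14 if they kept it, yet it differed by 0.17 on day 3. The median of 14 keratinocyte markers was 0.25, but Krt5 was 5.68-fold higher on day 1 and 3.33-fold on day 3. Of the 14, 2 and 1 were at least 4-fold higher on these days, so a smaller share stays open. Urothelial cells as the whole source would bring Upk1a and Upk3a if they kept them, yet the log2 ratios of these genes were -0.95 and -1.42. The median of 12 urothelial markers was 0.26, but Upk3b, 1 of the 12, was at least 4-fold higher. Here too a smaller share stays open. Cells of either kind that lost their markers in culture cannot be seen this way, so they stay open as well. Levels on the array that had been set in advance for both were dropped, as signals of different probes cannot be compared. Without the Sprr2 genes the median of the other 34 cornified envelope genes on day 3 was 0.68. Reference gene scaling lowers that median by 0.25, to under the bound set in advance. Of the 34, 11 were at least 4-fold higher on day 3 and 1 at least 4-fold lower, so signal shared within that family did not account for the whole pattern. Expression of these genes by the cultured cells themselves may be the source, a hypothesis formed on these arrays and not tested on others.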

How the results depend on the processing

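The alternative without the multiplicative trend correction was chosen after the data had been seen, the rest were chosen before the data were examined, and the cause of the differences below was not tested except where the construction gives it. The counts of genes moved by construction with the threshold. At 2-fold, 2557 genes were higher and 2887 lower on day 1 against day 0, 3152 and 4141 on day 3 against day 0, and 1322 and 1561 on day 3 against day 1, and at 8-fold the counts were 207 and 354, 438 and 634, and 119 and 67. With spike-in scaling, 1748 genes were higher and 936 lower on day 3 against day 0, and 494 and 148 on day 3 against day 1, and with normexp 132 were lower on day 3 against day 1. The other counts at 4-fold stayed within 1.5 times the main ones. The proximal tubule marker median was -2.65 with median centring and -3.18 with reference gene scaling on day 1, and on day 3 it was -5.41 and -5.97 with these, -5.23 with spike-in scaling and -5.06 with the mean of probes. On day 1 the injury median was 2.04 with median centring and 1.502 with reference gene scaling, and the interferon median 1.56 and 1.03. The G2/M median of day 3 against day 1 was 4.50 with spike-in scaling. Over the alternatives computed for each, no named gene at least 4-fold different and no list median of 1 or more in size took the other sign. Of 126 list medians, 26 took the other sign under some alternative, the largest of them 0.30 in size. Of 342 ratios of named genes of at least 4-fold, 298 were so under all alternatives computed for single genes. Those limited to genes well above background on all 3 arrays, or without the filter on dim genes, were not. Of the computed ones, the authors' value table and keeping outlier spots moved no gene ratio beyond the spread between spots. The authors' value table, with spots that had an outlier flag left out here too, gave 640 and 974, 1017 and 1524, and 307 and 250 genes in the 3 comparisons. No spot was saturated, so that leaving out saturated spots tested nothing. No paired analysis was possible because each day has 1 array, and none could leave out a replicate. Signal over background limits the ratios of dim genes. These are bounds where the gene's probe was not well above background on an array. They are taken against 1.14%, 1.06% and 0.669% of the 75th percentile on the 3 arrays, or against the gene's own signal if higher.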

Other observations

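The genes given here were chosen after their values were seen, and no explanation was tested for them here. The 13 mesothelium genes measured, 4 of which other lists hold too, had medians of 0.10 on day 1 and 0.58 on day 3, with 3 and 5 of them at least 4-fold higher and 2 and 1 at least 4-fold lower. The day 1 median takes the other sign under some alternatives. Il24, a cytokine gene, was 10.7-fold higher on day 1 and 15.6-fold higher on day 3. Cldn16, a claudin of the loop of Henle, was 4.97-fold higher on day 3 than on day 1.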
